A study of Solanum lycopersicum with 20 samples.

How the data were processed

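RNA from tomato leaves was labelled with Cy3 and hybridised 1 sample per array to an Agilent 4x44k tomato array. Per the labels, plants grew at 24 °C with a 16 h photoperiod, 70% humidity and a light intensity of 350, RNA came from 100 mg of leaf, had an integrity number of at least 7, and 500 ng were labelled. The 20 arrays form 10 groups of 2 arrays: an untreated control without a stated time, and harpin (100 µg/ml), CSNP and H-CSNP at 24, 48 and 72 h. The doses of CSNP and H-CSNP are not given in the labels. The dye field of 6 samples reads Cy4 to Cy7, which was read as a filled-down entry, since each file holds 1 green channel.

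Per the file headers, the deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), with gProcessedSignal subtracted for background and detrended. The deposited series matrix holds log2 values of gProcessedSignal minus each array's 75th percentile, not centred per gene, with column medians from -3.328 to -2.74. When these values were computed again from the scanner files, at least 99.98% of the probes lay within 0.02 on each array. The arrays lay on 6 slides. The control had a slide of its own, read on another scanner 167 days before the first treated array. Harpin at 72 h had a slide of its own, and the others held harpin at 24 and 48 h, CSNP at 24 and 48 h, CSNP at 72 h with H-CSNP at 24 h, and H-CSNP at 48 and 72 h.

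Values were log2 of gProcessedSignal, averaged over replicate spots without outlier spots, minus the 75th percentile of the array. A probe was tested if both arrays of at least 1 group lay well above background, which kept 32978 of 43603 probes and left out 10625. Per array 62.36% to 75.55% of the probes lay well above background, 235 to 502 spots were saturated, and the 75th percentile ranged from 552.27 to 1405.5. A fold change against a group with an array not above background (set to at least the lowest level well above background on that array), or with saturated arrays, is given as a bound ("at least") where called. The standard deviation between the replicates of a group (root mean square over probes) was 0.197 to 0.542, highest in the control.

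Probes were paired with products from the deposited array annotation and the RefSeq accessions. Of 2329 probes with a RefSeq accession 2233 matched and 96 did not. In all 4185 probes of 2480 gene names had a product, named from RefSeq (2275), by sequence similarity over at least 30% of its length (1535), from GenBank (211) or from the gene name (164). Products named by similarity are written "similar to". A further 39418 probes had no product and, apart from TA56870_4081, are not named. Each gene stands for its brightest probe.

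All statistics used R 4.3.3 with limma 3.58.1 and the package data.table (1.17.8). A linear model with 1 mean per group was fitted to all 20 arrays (10 residual degrees of freedom), and 19 contrasts were tested with moderated statistics (eBayes), two-sided, with Benjamini-Hochberg adjustment over the probes tested. These are the 9 comparisons with the control, H-CSNP against harpin and against CSNP at each time, the changes with time within a slide and their interaction. The 3 overall comparisons of treatments used the 12 arrays of both treatments with time as a term (8 residual degrees of freedom). Probes with an adjusted p below 0.05 were called. Each p in the report is an adjusted p from limma, from its functions eBayes or camera. An error after ± is the standard error from limma.

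Of 27 gene lists, defined by words in the product before the data were examined, 23 held at least 5 measured genes and were tested with camera (limma) at an inter-gene correlation of 0.01, adjusted over 506 tests. Camera with an estimated correlation and fry, which tests a list alone and does not compare it with other genes, were the alternatives. Genes were named by a rule set before the data were examined. For each treatment against the control, these are the 8 highest and 8 lowest mean changes among genes called at all 3 times. Added to them are the 8 highest and 8 lowest of each overall comparison, the 6 highest and 6 lowest of each comparison of times and of the interaction, and the 4 highest and 4 lowest of each H-CSNP comparison at a single time. For each list and comparison up to 4 members with the smallest p were named, and sentinel defence genes at any value. Genes of low rank were left out for length.

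The procedure was tested on simulated data. Of 100 probes changed by 1 on the log2 scale, 30% were called in a comparison of 2 with 2 arrays and 71% in an overall comparison. At a change of 2 these were 79% and 93%, with 6 false calls among 32876 probes in each. The simulated arrays had the same spread per probe in every group and no slide effect. In the data the replicate standard deviation ranged from 0.197 to 0.542, so these rates need not hold for each comparison. Comparisons that share the control were set beside arrays simulated without any effect, in which 0 probes were called by limma.

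Alternatives chosen before the data were examined were normexp background correction (offset 50), quantile normalization, no filter on dim probes, only probes well above background on all arrays, a common floor, a replicate block, the deposited series matrix, eBayes with trend and robust, a fit to only the arrays compared, slide as a block and the omission of each array. Fits without the 72 h arrays, and for the gene lists normexp, quantile normalization and the omission of saturated probes, were chosen after seeing the data. Spike-in probes were used for no comparison.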

Results

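Leaves of tomato cv. Arka vikas were profiled on Agilent 1-colour arrays after treatment with the bacterial protein harpin, with chitosan nanoparticles (CSNP) or with harpin-loaded chitosan nanoparticles (H-CSNP). Per the labels, leaves of 3 plants were pooled per treated sample, the experiment was carried out 2 times, and harpin was given at 100 µg/ml. The 20 arrays fall into 10 groups of 2: an untreated control without a time, and each of the 3 treatments at 24, 48 and 72 h. Between 62.36% and 75.55% of the probes lay well above background on an array, and the 75th percentile of the deposited processed signal ranged from 552.27 to 1405.5. The number of arrays limits the precision. The median standard error of a log2 fold change between groups of 2 was 0.269. It pools the spread of all 10 groups and does not measure that of the 2 groups compared. The replicate standard deviation ranged from 0.197 (H-CSNP at 24 h) to 0.542 (control).

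Each value below is a log2 fold change from limma, with n = 2 arrays against 2 unless stated, and each p is adjusted over the 32978 probes tested. In the 714 calls of the named genes between 2 groups, both arrays of the first group lay beyond both arrays of the second, which 33.3% of the possible splits of 4 arrays give by chance. The calls were selected on the same values, so this separation adds no support. "Called" means an adjusted p below 0.05. Fits to only the arrays compared, which estimate the variance from those arrays alone, ended 199 of the gene results read here, most of them at 72 h. When 1 array was left out, the fold moved by over 1.5 times in 86 of 632 named-gene calls against the control and in 12 of 86 between treated groups or times.

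The first question was which leaf transcripts changed after harpin, a protein that sets off defence and cell death in plants. Several pathogenesis-related (PR) transcripts were higher after harpin at 24 h than in the control. The control had its own slide and scan, from which the treatment cannot be told apart. PR-1a1, a salicylate-responsive PR-1 protein, rose at least 4.84-fold at 24 h (adjusted p = 0.000954), as neither control array lay above background, and was not called at 48 h (adjusted p = 0.663) or 72 h (adjusted p = 0.739). PR1b1, another PR-1 protein, rose by 1.70 ± 0.43 at 24 h (adjusted p = 0.0073) and measured -0.09 at 48 h and -0.58 at 72 h, both uncalled. The PR5-like gene NM_001247422 rose at least 5.56-fold at 24 h (adjusted p = 0.00803). GluB, a glucanase that cuts fungal wall glucans, rose by 3.34 ± 1.18 at 24 h (adjusted p = 0.0351), and 12 of its 12 other probes were called higher. The chitinase CHI9 rose by 1.66 ± 0.43 at 24 h (adjusted p = 0.008), with 4 of 4 other probes called higher, and was not called at 48 or 72 h. With normexp background correction the calls of PR-1a1 (adjusted p = 0.0926) and NM_001247422 (adjusted p = 0.0753) ended, and without the filter on dim probes that of GluB ended (adjusted p = 0.0507). Leaving out replicate 2 of the harpin 24 h arrays ended the calls of PR1b1 (adjusted p = 0.0724), CHI9 (adjusted p = 0.0514) and NM_001247422 (adjusted p = 0.0546), and each of the 4 possible omissions ended that of GluB (adjusted p up to 0.165).

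Other PR genes fell under harpin at the later times. PR-P2, a PR-4 protein, fell by 2.98 ± 0.33 at 48 h (adjusted p = 8.72e-05) and by 3.18 ± 0.33 at 72 h (adjusted p = 3.6e-05). P4, a PR-1 protein, fell at least 5.69-fold at 48 h (adjusted p = 0.00117) and at least 3.84-fold at 72 h, while at 24 h it measured 0.25 (adjusted p = 0.796). TA36002_4081, similar to a PR leaf protein 4 precursor, fell at least 7.98-fold at 48 h and at least 5.39-fold at 72 h. CK348294, similar to a PR leaf protein 6 precursor, fell at least 12.3-fold at 48 h (adjusted p = 0.00318) and at least 10.6-fold at 72 h. The call of P4 at 48 h ended with normexp (adjusted p = 0.0642). Threonine deaminase Td, an enzyme of isoleucine synthesis that also acts in defence against herbivores, fell at least 121-fold at 48 h (adjusted p = 0.00497). It was not called at 24 h (adjusted p = 0.388) or 72 h (adjusted p = 0.313).

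Among genes called at all 3 times under harpin, TA54846_4081, similar to an Sn-1 protein, rose by 2.37, 4.09 and 3.51 at 24, 48 and 72 h (standard error 0.46, adjusted p = 0.0017, 9.38e-05 and 0.000161). TA35695_4081, similar to polyphenol oxidase E, which makes leaf tissue less digestible, rose by 2.52, 3.33 and 2.10 (standard error 0.61). SODCP.2, a superoxide dismutase that removes superoxide, rose by 2.55, 2.74 and 2.75 (standard error 0.39). MTS1, a monoterpene synthase, rose by 2.18, 3.06 and 2.37 (standard error 0.57). TA55074_4081, similar to a sulfate transporter, rose by 3.56, 2.09 and 3.34 (standard error 0.55), whereas the sulfate transporter ST2 fell by 3.20, 1.98 and 3.04 (standard error 0.71). CHS1, chalcone synthase at the entry of the flavonoid pathway, fell by 3.61, 2.75 and 3.28 (standard error 0.52). ARPI, a proteinase inhibitor of the wound response, fell by 4.17, 3.89 and 3.25 (standard error 0.63). The mitochondrial small heat shock protein MTSHP fell by 4.22, 2.56 and 2.59 (standard error 0.52), and the chitin-binding lectin AB360604 by 4.62, 4.40 and 3.94 (standard error 1.12). Leaving out replicate 2 of the harpin 72 h arrays left 1.06 for TA35695_4081 at 72 h (adjusted p = 0.177) and 1.29 for MTS1 there (adjusted p = 0.0577). Without replicate 2 of the control, the calls of TA55074_4081 at 48 h (1.21, adjusted p = 0.145), ST2 at 48 h (adjusted p = 0.195) and AB360604 at 48 and 72 h (adjusted p = 0.0737 and 0.0938) ended. The call of MTS1 at 24 h ended with normexp (adjusted p = 0.0657) and without replicate 2 of harpin 24 h (adjusted p = 0.0697), and those of ST2 ended at 48 h without the filter on dim probes (adjusted p = 0.0649) and at 72 h without replicate 1 of harpin 72 h (adjusted p = 0.051).

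Among further genes under harpin, WRKY40, a transcription factor of the immune response, rose by 1.65, 1.35 and 1.09 at 24, 48 and 72 h (standard error 0.22), and the kinase MAPK14 by 2.19, 2.01 and 2.24 (standard error 0.30). IAA11, an auxin response repressor, rose by 1.84, 2.09 and 1.84 (standard error 0.20), and the auxin response factor ARF5 fell by 2.37, 1.10 and 1.34 (standard error 0.18). PCNA, the clamp of DNA replication, fell by 2.19, 2.29 and 1.94 (standard error 0.26), and TAS14, a dehydrin of the drought response, by 2.58, 2.46 and 1.96 (standard error 0.33). ACS6, an enzyme of ethylene synthesis, rose by 0.97, 0.99 and 1.03 (standard error 0.19). BE450306, similar to 12-oxophytodienoate reductase 1, rose at least 4.58-fold, 3.52-fold and 3.38-fold, with its calls at 48 and 72 h lost under normexp (adjusted p = 0.14 and 0.117) and when 1 array was left out (adjusted p up to 0.103 and 0.0692). Normexp also ended the call of ARF5 at 48 h (adjusted p = 0.0864). Limma called 14478 probes at 24 h (7851 higher, 6627 lower), 10940 at 48 h (6301 higher, 4639 lower) and 13942 at 72 h (7151 higher, 6791 lower), and 8733 to 16200, 4651 to 13308 and 8244 to 15684 when 1 array was left out. With normexp the 5231 calls at 48 h were 2271 higher and 2960 lower, and the median of all probes moved from 0.109 to -0.186. With only the arrays compared in the fit, the 1996 calls at 72 h were 685 higher and 1311 lower. Both control arrays lay on a slide of their own, read on another scanner 167 days before the first treated arrays, so treatment, slide, labelling and scan cannot be told apart here.

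The second question was what the particles without harpin changed. After CSNP, a carrier made from the deacetylated form of chitin, AI780922, similar to an auxin repressed and dormancy associated protein, rose by 1.66, 4.17 and 2.96 at 24, 48 and 72 h (standard error 0.53, adjusted p = 0.0252, 7.99e-05 and 0.000957). TA54846_4081 rose by 2.75, 2.88 and 3.19 (standard error 0.46), SODCP.2 by 2.80, 2.79 and 2.95 (standard error 0.39) and TA35695_4081 by 2.73, 2.13 and 2.90 (standard error 0.61). BG130524, similar to an endochitinase precursor, rose by 2.20, 1.91 and 2.01 (standard error 0.46), while the chitinase CHI3 fell by 2.19 ± 0.67 at 48 h (adjusted p = 0.0181) and CHI9 measured 1.04 at 24 h (adjusted p = 0.0707), with 3 of 4 other probes called higher. CHS1 fell by 3.76, 4.54 and 3.60 (standard error 0.52), ARPI by 4.05, 4.04 and 3.78 (standard error 0.63) and ST2 by 2.38 and 2.74 at 24 and 72 h (standard error 0.71) and at least 15.6-fold at 48 h. TA37448_4081, similar to a lipid-transfer protein, fell by 5.16, 3.17 and 3.48 (standard error 0.83), and AB360604 fell by 4.25 ± 1.12 at 24 h and at least 21.6-fold at 72 h. TA38853_4081, similar to a class II small heat shock protein, fell at least 62.3-fold at 24 h, at least 38-fold at 48 h and at least 27.8-fold at 72 h. The call of AI780922 at 24 h ended with normexp (adjusted p = 0.0792) and without replicate 2 of the control (adjusted p = 0.18). Single omissions also ended the calls of CHI3 (adjusted p up to 0.0733) and TA37448_4081 at 48 h (adjusted p = 0.0617), of TA35695_4081 at 48 h (adjusted p = 0.0592), of ST2 at 24 and 72 h (adjusted p up to 0.14 and 0.0564) and of AB360604 at 24 h (adjusted p = 0.0774).

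Some PR genes fell under CSNP at 24 and 72 h and were not called at 48 h, while 3 of the 15 PR genes rose at each time. PR-P2 fell by 2.85 ± 0.33 at 24 h (adjusted p = 9.61e-05) and by 2.09 ± 0.33 at 72 h (adjusted p = 0.000484). TA36002_4081 fell at least 6.79-fold at 24 h and at least 4.72-fold at 72 h, and measured -0.41 at 48 h (adjusted p = 0.672). P4 fell at least 4.84-fold at 24 h and at least 3.37-fold at 72 h, and measured -0.40 at 48 h (adjusted p = 0.675). CK348294 fell at least 7.3-fold at 24 h (adjusted p = 0.0173), measured -1.18 at 48 h (adjusted p = 0.323) and fell at least 9.32-fold at 72 h. Normexp ended the calls of P4 (adjusted p = 0.267 and 0.194) and TA36002_4081 (adjusted p = 0.167 and 0.158) at 24 and 72 h, and leaving out replicate 2 of CSNP 24 h ended that of CK348294 at 24 h (adjusted p = 0.147). PR1b1 was not called at 24, 48 or 72 h (adjusted p = 0.332, 0.657 and 0.0834). Limma called 12716 probes at 24 h (6863 higher, 5853 lower), 15348 at 48 h (7985 higher, 7363 lower) and 15004 at 72 h (8290 higher, 6714 lower), again with slide, labelling and scan of the control apart. When 1 array was left out these were 6545 to 14770, 10125 to 16684 and 9001 to 16300.

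The third question was what the loaded particles changed. After H-CSNP, cevi16, a peroxidase of the kind that builds wall polymers and uses hydrogen peroxide, rose by 3.77, 2.22 and 1.13 at 24, 48 and 72 h (standard error 0.41, adjusted p = 3.45e-05, 0.00216 and 0.048). XTH9, a xyloglucan-modifying wall enzyme, rose by 2.54, 2.32 and 1.83 (standard error 0.41). TA54846_4081 rose by 1.89, 4.17 and 3.30 (standard error 0.46), TA35695_4081 by 2.47, 3.56 and 2.92 (standard error 0.61) and SODCP.2 by 1.39, 2.71 and 3.28 (standard error 0.39). CHS1 fell by 4.53, 3.69 and 3.02 (standard error 0.52), NM_001246984, a class II small heat shock protein, by 4.19, 2.57 and 2.30 (standard error 0.35), and TA37448_4081 by 3.38 and 3.86 at 24 and 72 h (standard error 0.83) and at least 62-fold at 48 h. ARPI fell by 5.25 ± 0.63 at 24 h (adjusted p = 6.28e-05) and by 3.65 ± 0.63 at 72 h (adjusted p = 0.0012), and measured 0.08 at 48 h (adjusted p = 0.942). The call of cevi16 at 72 h ended with normexp, with quantile normalization and without the filter on dim probes (adjusted p = 0.215, 0.106 and 0.0683) as well as without replicate 2 of H-CSNP 72 h (0.73, adjusted p = 0.306), and that of TA54846_4081 at 24 h ended with normexp (adjusted p = 0.081). Leaving out replicate 1 of the control ended the call of SODCP.2 at 24 h (adjusted p = 0.0582).

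GluB and CHI9, which rose at 24 h under harpin, also rose at 24 h under H-CSNP, by 3.42 ± 1.18 (adjusted p = 0.0283) and 2.06 ± 0.43 (adjusted p = 0.00196). Of their other probes, 11 of 12 and 4 of 4 were called higher. PR-1a1 rose at least 1.52-fold at 24 h (adjusted p = 0.013), but with normexp its direction turned and the call ended (adjusted p = 0.831), as it did without replicate 1 of H-CSNP 24 h (adjusted p = 0.077). PR-P2 fell by 2.03, 3.01 and 2.70 at 24, 48 and 72 h (standard error 0.33, adjusted p = 0.00045, 9.47e-05 and 0.000182). P4 fell at least 4.98-fold, 5.11-fold and 5.18-fold, and TA36002_4081 at least 6.87-fold, 7.16-fold and 7.26-fold. The call of P4 at 72 h ended with normexp (adjusted p = 0.0633), and each omission of 1 array ended that of GluB (adjusted p up to 0.108). BG130524 measured 0.04 at 24 h (adjusted p = 0.955) and rose by 2.20 at 48 h and 2.41 at 72 h (standard error 0.46). AOS, allene oxide synthase of the jasmonate pathway, fell at least 4.06-fold at 24 h (adjusted p = 0.0152), at least 3.99-fold at 48 h (adjusted p = 0.0283) and at least 3.43-fold at 72 h (adjusted p = 0.0469), calls that ended with normexp (adjusted p = 0.0706, 0.133 and 0.262), at 48 and 72 h with quantile normalization (adjusted p = 0.0528 and 0.058) and when 1 array was left out (adjusted p up to 0.0769, 0.115 and 0.319). Limma called 16592 probes at 24 h (8538 higher, 8054 lower), 8361 at 48 h (4105 higher, 4256 lower) and 11256 at 72 h (6244 higher, 5012 lower), and 10448 to 18009, 3724 to 10386 and 6190 to 13499 when 1 array was left out. With normexp the 10088 calls at 24 h were 4199 higher and 5889 lower. The slide, labelling and scan of the control again differ from those of the treated arrays.

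**Figure D1:**
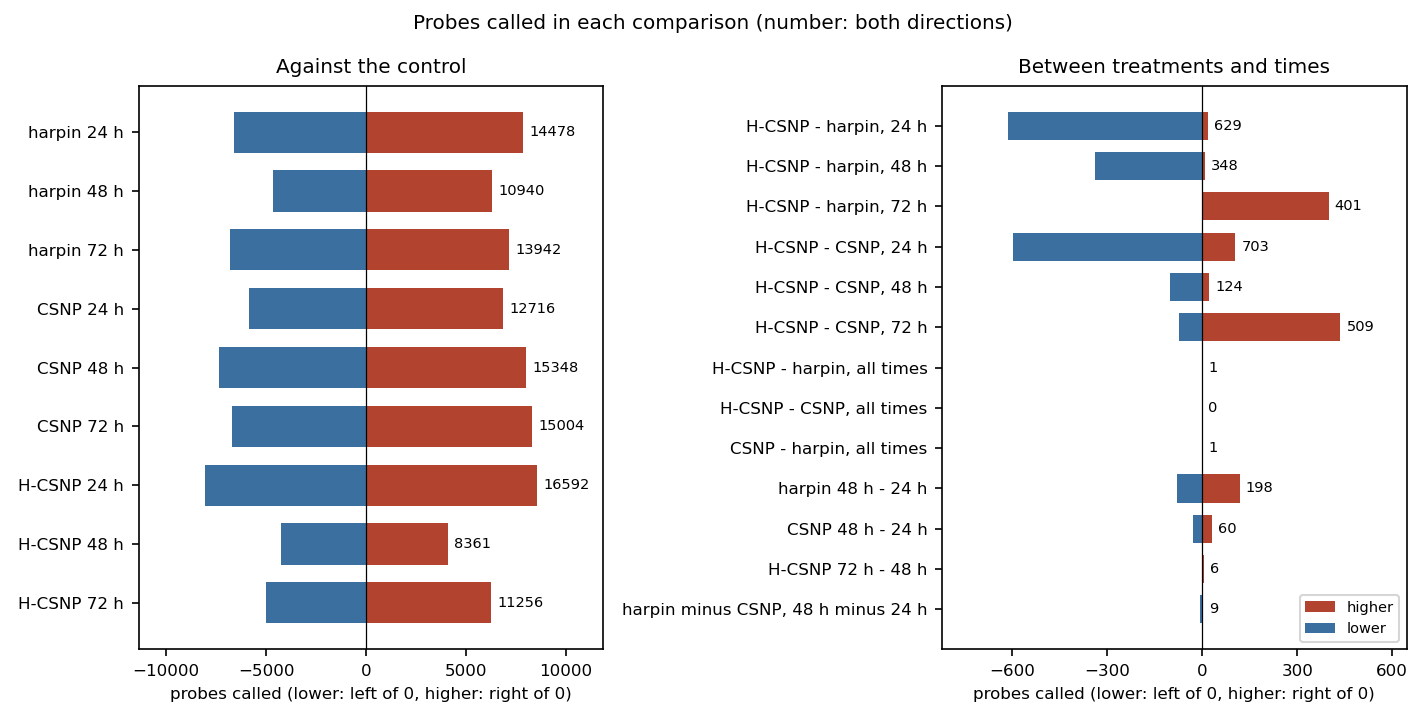
Probes called higher or lower (bars, number of probes) in each comparison, with the comparisons against the control in the left panel and those between treated groups or times in the right panel. Counts against the control lie between 8361 and 16592, and those between treated groups lie at or below 703.

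Several genes were called in the same direction in each of the 9 comparisons with the control. TA55118_4081, similar to a low temperature and salt responsive protein, rose at least 4.14-fold to at least 8.23-fold (with normexp adjusted p = 0.0517 in H-CSNP at 48 h), and NM_001247110, described as expressed predominantly in leaves, by 2.03 to 3.45 (standard error 0.40). THT7-8, a transferase that makes hydroxycinnamic acid amides for the wall, rose by 1.59 to 2.66 (standard error 0.20). EF121545, an auxin response factor, rose by 1.39 to 1.97 (standard error 0.21). NM_001247455, MADS-box protein 5 of flower development, fell at least 20-fold in each. BI934053, similar to an ascorbate oxidase, fell at least 5.76-fold to at least 11.1-fold, with the calls in harpin at 24 h, CSNP at 24 and 72 h and H-CSNP at 72 h lost under normexp (adjusted p = 0.097, 0.218, 0.0924 and 0.0558). Of all probes, 2360 were called higher and 2338 lower in all 9 comparisons, against 0.0251 and 0.00742 expected if the calls were independent. The same 2 control arrays enter each comparison, and simulated arrays without any treatment effect gave a correlation of 0.499 between the comparisons, beside 0.854 observed, and a covariance of 0.073, beside 0.86 observed. The control group cannot be split into parts of 2 arrays each, so part or all of the excess may come from the shared controls. The simulated arrays held no offset for the slide, labelling and scan of the control, which all 9 comparisons would share. At all 3 times, harpin shared 4419 higher and 3658 lower probes (325 and 192 expected), CSNP 5186 and 3898 (418 and 266 expected) and H-CSNP 2686 and 2976 (201 and 158 expected).

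Many ribosomal protein genes fell against the control in all 9 comparisons. Of 90 genes, 58, 52 and 59 fell under harpin at 24, 48 and 72 h, 49, 73 and 67 under CSNP and 72, 42 and 46 under H-CSNP, while 1 rose in each comparison. Adjusted over the list alone, 61, 62, 65, 53, 75, 68, 75, 50 and 48 fell. Their medians lay between -1.05 and -0.62. ACI39, ribosomal protein S13, fell by 1.12 to 1.41 (standard error 0.17) where it is listed, and AW626328, similar to ribosomal protein S7, by 1.13 to 1.90 (standard error 0.20). A gene is listed in a comparison for its small p or large change. A range over listed comparisons can therefore leave out those in which the gene ranked lower. Camera placed the list below the other genes, from adjusted p = 7.46e-14 for CSNP at 48 h to 6.58e-08 for CSNP at 24 h, and with an estimated correlation adjusted p = 0.783 to 0.899.

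Many heat shock protein genes fell too. Of 34 genes, 21, 16 and 19 fell under harpin at 24, 48 and 72 h, 18, 20 and 20 under CSNP and 21, 15 and 18 under H-CSNP, and 2 or 3 rose. Adjusted over the list alone, 22, 19, 20, 18, 21, 20, 21, 17 and 19 fell. The chaperone ER21, an ethylene-responsive HSP70 cognate, fell by 1.54 to 2.74 (standard error 0.24) in the 8 comparisons in which it is listed, while NM_001246906, a heat shock protein binding protein, rose by 1.63 to 2.65 (standard error 0.23) at 48 and 72 h of each treatment. The list medians lay between -1.13 and -0.71, and -1.01 replaced -1.13 (H-CSNP, 24 h) with dim members at their bound. Camera gave adjusted p = 5.29e-05 for harpin at 24 h to 0.00496 for harpin at 72 h, and with an estimated correlation adjusted p = 0.783 in all 9.

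More cell wall expansin and xyloglucan enzyme genes rose than fell. Of 56 genes, 19, 23 and 18 rose under harpin at 24, 48 and 72 h, 27, 27 and 18 under CSNP and 19, 19 and 25 under H-CSNP, against 1 to 10 that fell. EXLA1, an expansin-like protein, rose by 1.51 ± 0.18 under harpin and 1.76 ± 0.18 under H-CSNP at 24 h, and XTH3 by 1.85 ± 0.25 under harpin and 1.77 ± 0.25 under CSNP at 24 h. The medians lay between 0.42 and 0.78. Once dim members were set to their bound, 0.25 replaced 0.44 for harpin at 24 h and 0.29 replaced 0.50 for harpin at 72 h. Camera gave adjusted p = 2.38e-05 for H-CSNP at 72 h to 0.0263 for H-CSNP at 24 h, and with an estimated correlation adjusted p = 0.639 to 0.783. Without saturated probes the call for H-CSNP at 24 h ended (adjusted p = 0.0532), and with normexp the median there was 0.09.

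Some phenylpropanoid genes, which supply lignin and wall-bound phenolics, rose at 24 h. Of 17 genes, 7 rose under harpin, 7 under CSNP and 10 under H-CSNP at 24 h, and adjusted over the list alone 8 rose and 1 fell under CSNP. THT7-1 rose by 1.13, 0.98 and 0.90 at 24 h (standard error 0.16) and TA36572_4081, similar to caffeoyl-CoA O-methyltransferase, by 1.62, 1.89 and 1.23 (standard error 0.22), for harpin, CSNP and H-CSNP. The list medians were 0.52, 0.62 and 0.90, with camera adjusted p = 0.0172, 0.0105 and 0.00283, and with an estimated correlation adjusted p = 0.783, 0.777 and 0.639. At 48 and 72 h camera called the list in no comparison with the control. Of 6 flavonoid genes, 4, 3 and 5 fell under harpin at 24, 48 and 72 h, 4, 5 and 4 under CSNP and 5, 3 and 3 under H-CSNP. An2, a regulator of anthocyanins, fell at least 3-fold at 24 h and by 1.95 and 1.21 at 48 and 72 h under harpin (standard error 0.27), calls that ended with normexp (adjusted p = 0.464, 0.0525 and 0.109), and TA49536_4081, similar to flavonoid 3'-monooxygenase, by 1.71, 1.30 and 1.90 (standard error 0.40), with the call at 48 h lost without replicate 2 of the control (adjusted p = 0.114). Camera called the flavonoid list for CSNP at 48 h (median -2.37, adjusted p = 0.0351), and the adjusted p = 0.783 with an estimated correlation. This call ended with normexp (adjusted p = 0.0724) and with quantile normalization (adjusted p = 0.0591).

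**Figure D2:**
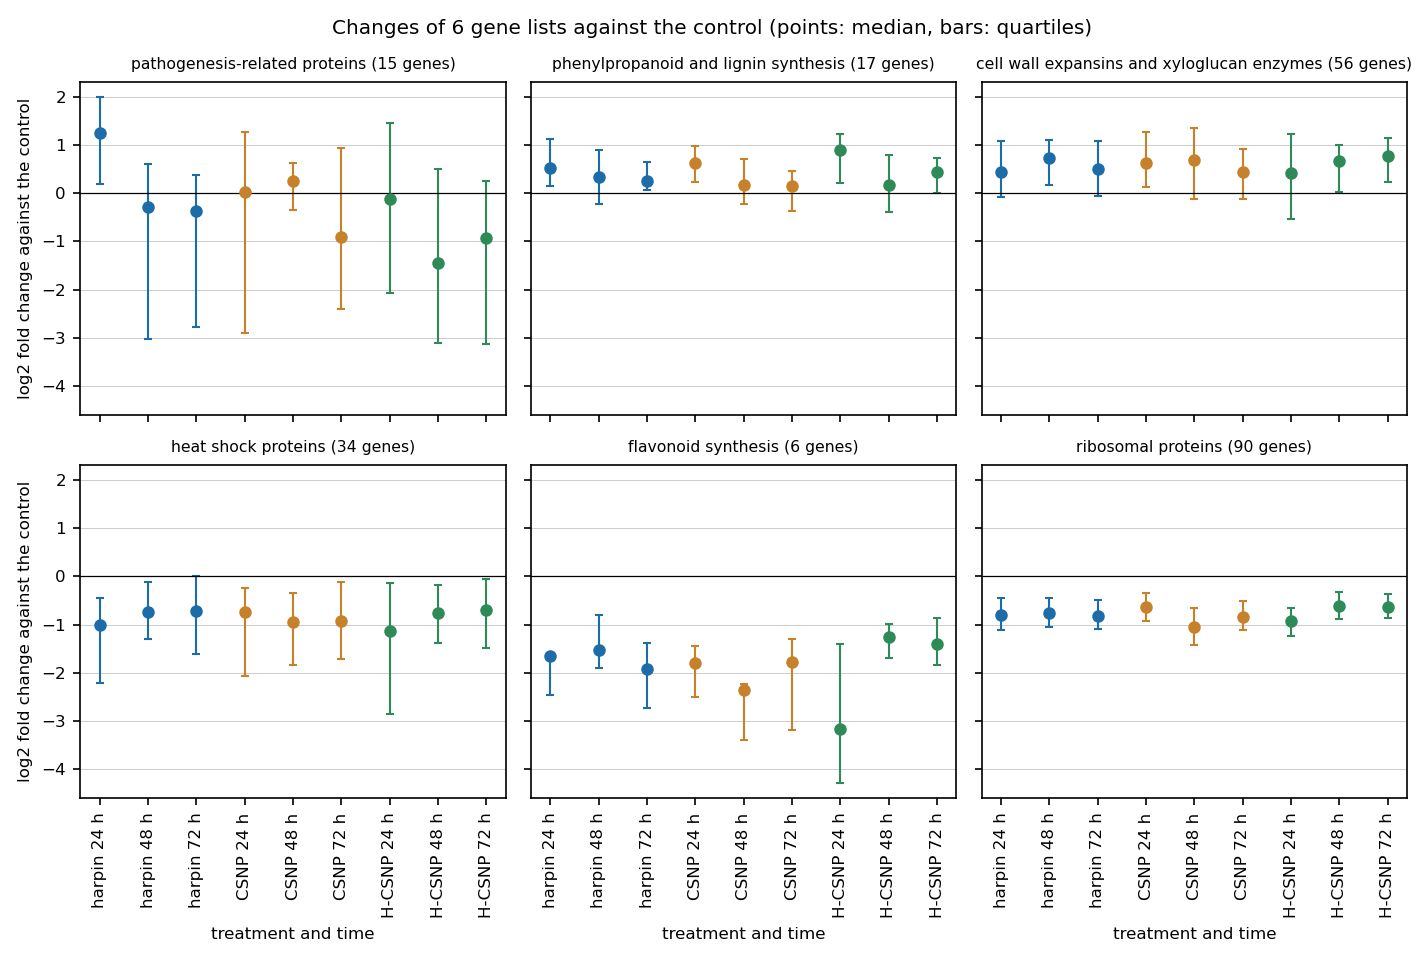
Median log2 fold change against the control (points) with the lower and upper quartile over member genes (bars) for 6 gene lists at 24, 48 and 72 h of each treatment. Ribosomal protein medians lie between -1.05 and -0.62, cell wall medians between 0.42 and 0.78.

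The list of PR proteins held 15 genes. Among them P4 and TA36002_4081, with similar product names, had close levels in every group. In the control they measured -3.61 and -3.13, and under harpin at 48 h -7.82 and -8.23. Whether they are the same transcript was not tested, so counts and list tests of PR genes may include it more than once. Under harpin 7 rose and none fell at 24 h, 2 rose and 5 fell at 48 h, and 1 rose and 6 fell at 72 h. Under CSNP 3 rose and 6 fell at 24 h, 3 rose at 48 h, and 3 rose and 7 fell at 72 h, and under H-CSNP 5 rose and 6 fell, 1 rose and 6 fell, and 2 rose and 6 fell. Adjusted over the list alone the counts differed for H-CSNP at 48 h, with 2 that rose. The median was 1.25 for harpin at 24 h and -1.44 for H-CSNP at 48 h (-1.10 with dim members at their bound), and for CSNP at 24 h the median of 0.03 and the mean of -0.73 differ in sign. Camera called this list in none of the 9 comparisons with the control (adjusted p = 0.083 for harpin at 24 h), and with normexp it was called for harpin at 24 h (adjusted p = 0.0314) with a median of 0.34. Of 55 photosynthesis genes 31 were saturated. Among the other 24, 1 rose and 5 fell under harpin at 24 h, with camera adjusted p = 0.307, and no comparison with the control was called without saturated probes. BP897166, similar to a Rubisco small chain, rose by 0.89 to 1.76 (standard error 0.24) in all 9, with the call for H-CSNP at 24 h lost without replicate 2 of the control (adjusted p = 0.0695).

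Other lists split. Of 38 ethylene genes, 10 rose and 12 fell under harpin at 24 h. ERF1, an ethylene-responsive factor, rose by 1.69 ± 0.23 and ERF4 by 1.21 ± 0.18 under harpin at 24 h, while the receptor homolog ETR4 fell by 1.42 ± 0.21 at 48 h. Of 45 peroxidase, oxidase and antioxidant genes, 9 rose and 16 fell under H-CSNP at 24 h. AW216562, similar to a cationic peroxidase, rose at least 31.6-fold there (adjusted p = 1.15e-05), and FESOD, an iron superoxide dismutase, fell by 1.77 ± 0.26 under harpin at 24 h. Of 24 salicylate and immune receptor genes, 3 rose and 5 fell under harpin at 24 h, and BP882049, similar to the kinase partner Prf, fell by 0.69 to 1.13 (standard error 0.19) in all 9, with the calls for CSNP at 24 h and H-CSNP at 72 h lost under normexp (adjusted p = 0.0839 and 0.0666) and those for CSNP at 24 h and H-CSNP at 48 and 72 h lost when 1 array was left out (adjusted p = 0.0678, 0.0893 and 0.112). Of 18 jasmonate genes 2 rose and none fell under harpin at 24 h. The lipoxygenase loxD rose by 1.15 ± 0.26 under H-CSNP at 48 h (adjusted p = 0.0066). Counts for harpin at 24 h were 4 higher and 2 lower of 11 chitinases, 4 and 5 of 24 proteinase inhibitor and wound genes, 1 and 2 of 10 glutathione S-transferases, 1 and 2 of 7 WRKY factors, 7 and 4 of 28 MAP kinases and receptor kinases, 6 and 5 of 29 calcium genes, none and 2 of 9 ABA genes, 7 and 7 of 42 histone and cell cycle genes, 7 and 6 of 32 terpenoid genes, 4 and 2 of 19 clock genes and 7 and 7 of 34 auxin genes. Lists of 1 senescence gene and of 3 trichome, 3 vascular and 3 root markers were too short for camera. The senescence gene rose by 1.04 under H-CSNP at 48 h and was not called in the other 8 comparisons with the control. At 24 h, 1 vascular marker fell under harpin, 1 trichome marker under H-CSNP and 1 root marker under CSNP. Of 23 pollen, flower and fruit markers 3 rose and 11 fell under CSNP at 72 h, and camera called the list there (adjusted p = 0.0485), and with an estimated correlation adjusted p = 0.783, with quantile normalization adjusted p = 0.109 and with normexp adjusted p = 0.153.

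Whether loading changed the response to harpin was asked by comparing H-CSNP with harpin at each time. At 24 h some PR genes were lower after H-CSNP. CK348294 was lower by 4.42 ± 0.95 (adjusted p = 0.0314) and PR1b1 by 1.95 ± 0.43 (adjusted p = 0.0371). TA36002_4081 was at least 7.62-fold lower (adjusted p = 0.0247) and P4 at least 5.94-fold lower (adjusted p = 0.0308). These 4 of the 15 PR genes were called, and 8 were lower when adjusted over the list alone, with a list median of -1.35 and a camera adjusted p = 1.4e-05, and with an estimated correlation adjusted p = 0.105. The calls of CK348294 and PR1b1 ended without the filter on dim probes (adjusted p = 0.0506 and 0.0589), those of PR1b1, TA36002_4081 and P4 with normexp (adjusted p = 0.0832, 0.165 and 0.206), and all 4 when any 1 of the 4 arrays was left out (adjusted p up to 0.253, 0.337, 0.263 and 0.305). BP902045, similar to chloroplast ribosomal protein L17, was lower by 2.81 ± 0.34 (adjusted p = 0.000756), BG125071, similar to an auxin-regulated protein, by 2.58 ± 0.23 (adjusted p = 0.000261) and TC245073, similar to a dehydrin, by 2.20 ± 0.20 (adjusted p = 0.000261). Limma called 629 probes, 17 higher and 612 lower, against 187 to 237 when any 1 array was left out and 148 with normexp. Over these 612 probes the group median was -5.28 in H-CSNP at 24 h, -5.09 in CSNP at 72 h on the same slide and -5.19 in harpin at 72 h on another slide, against -3.91 to -3.31 in the others.

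At 48 h ARPI was higher after H-CSNP than after harpin by 3.96 ± 0.63 (adjusted p = 0.00815), and TA54822_4081, similar to a cytochrome b6/f subunit of photosynthetic electron transport, by 2.07 ± 0.34 (adjusted p = 0.0106). TA44246_4081, similar to MAP kinase phosphatase 1, which switches off stress kinases, was at least 3.07-fold lower (adjusted p = 0.0191), and MDC, an enzyme of isoprenoid synthesis, by 1.19 ± 0.22 (adjusted p = 0.0206). TC238184, similar to a hypersensitive-induced response protein, was lower by 1.28 ± 0.27 (adjusted p = 0.0379). With normexp the calls of TA44246_4081, MDC and TC238184 (adjusted p = 1.0 for each) and TA54822_4081 (adjusted p = 0.0673) ended, and that of TC238184 ended also with quantile normalization (adjusted p = 0.254). Omission of 1 array ended each call, with an adjusted p up to 0.105 for ARPI, 0.0872 for TA54822_4081 (1.30 and 2.84 without replicates 1 and 2 of harpin 48 h, both called), 0.176 for TA44246_4081, 0.204 for MDC and 0.423 for TC238184. Td measured 6.96 higher, at least 86-fold, without a call (adjusted p = 0.078). Of 24 proteinase inhibitor and wound genes 1 was higher, and 7 were higher and 1 lower adjusted over the list alone, with a median of 0.24 and a camera adjusted p = 0.000121, and with an estimated correlation adjusted p = 0.783. Limma called 348 probes, 8 higher and 340 lower, against 79 to 130 when any 1 array was left out, 2 higher and 0 lower with normexp (R package limma) and 19 higher and 124 lower with quantile normalization.

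At 72 h TC245073 was higher after H-CSNP than after harpin by 3.39 ± 0.20 (adjusted p = 4.18e-06), BP902045 by 3.43 ± 0.34 (adjusted p = 9.98e-05, and 2.84 without replicate 1 of harpin 72 h) and TC238749, similar to the vesicle-traffic protein ADP-ribosylation factor, by 3.33 ± 0.42 (adjusted p = 0.000681). TA57020_4081, similar to a photosystem II 10 kDa polypeptide, was higher by 2.28 ± 0.21 (adjusted p = 7.64e-05). XTH3 was higher by 1.19 ± 0.25 (adjusted p = 0.0368) and the transcription factor AP2d lower by 0.82 ± 0.18 (adjusted p = 0.0478), and both calls ended with normexp (adjusted p = 0.0642 and 0.249), without the filter on dim probes (adjusted p = 0.0664 and 0.0908) and when 1 array was left out (adjusted p up to 0.143 and 0.472). Limma called 401 probes, 399 higher and 2 lower, on different slides, and 241 and 846 without replicates 1 and 2 of harpin 72 h and 148 with normexp. In a fit to the compared arrays alone, limma called 0. None of the PR genes was called here. TC245073, BP902045, TC238749 and TA57020_4081 belong to the 612 probes lower in H-CSNP than in harpin at 24 h, which were also low in harpin and CSNP at 72 h, and 272 of these were called higher here.

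Comparison of H-CSNP with CSNP asked what harpin added to the particles. At 24 h NM_001247128, a glycine-rich protein of the cell wall type, was higher after H-CSNP by 3.17 ± 0.53 (adjusted p = 0.0068) and FRK2, a fructokinase, by 0.91 ± 0.18 (adjusted p = 0.0214). BG130524 was lower by 2.17 ± 0.46 (adjusted p = 0.0306), and cel5, an endoglucanase of wall loosening, by 2.80 ± 0.59 (adjusted p = 0.0285). BP902045 was lower by 2.99 ± 0.34 (adjusted p = 0.000517) and BI934404, similar to a chloroplast nucleoside diphosphate kinase, by 2.83 ± 0.27 (adjusted p = 0.000226). Limma called 703 probes, 104 higher and 599 lower, against 165 to 264 when any 1 array was left out. The call of BG130524 ended without the filter on dim probes (adjusted p = 0.0516). Omission of 1 array ended the calls of NM_001247128, FRK2, BG130524 and cel5 (adjusted p up to 0.0796, 0.207, 0.2 and 0.207), and not those of BP902045 and BI934404. These arrays lay on different slides, and 339 of the 612 probes lower in H-CSNP than in harpin at 24 h, BP902045 and BI934404 among them, were called lower here too. The same H-CSNP arrays enter both comparisons and served to select the 612 probes, so this overlap is partly built in.

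At 48 h some PR genes were lower after H-CSNP than after CSNP. PR-P2 was lower by 2.69 ± 0.33 (adjusted p = 0.0071), with 2 of 2 other probes called lower. NM_001247869, a glucanase, was at least 2.3-fold lower (adjusted p = 0.00494), TA36002_4081 at least 5.39-fold lower (adjusted p = 0.0219) and P4 at least 3.88-fold lower (adjusted p = 0.028). Of the 15 PR genes these 4 were lower, 6 adjusted over the list alone, with a median of -1.90 (-0.98 with dim members at their bound, -0.68 with normexp) and a camera adjusted p = 8.43e-09, and with an estimated correlation adjusted p = 0.0243. ARPI was higher by 4.11 ± 0.63 (adjusted p = 0.0176). ACI25, which inhibits fungal endoglucanases, was lower by 1.85 ± 0.21 (adjusted p = 0.00494), rnalx, a ribonuclease, by 1.82 ± 0.34 (adjusted p = 0.0408) and MADS1 by 1.57 ± 0.21 (adjusted p = 0.0089). The calls of NM_001247869, TA36002_4081, P4, ACI25 and MADS1 ended with normexp (adjusted p = 0.513, 0.185, 0.294, 0.127 and 0.309), and those of P4 and rnalx without the filter on dim probes (adjusted p = 0.0524 and 0.0726). Omission of replicate 1 of the H-CSNP 48 h arrays ended all of these calls, with an adjusted p = 0.0544 for PR-P2, 0.0516 for NM_001247869 and 0.19 for ARPI. Limma called 124 probes, 22 higher and 102 lower, on different slides, and 27 without replicate 2 of the H-CSNP 48 h arrays and 0 without replicate 1 (2714 at an unadjusted p below 0.05). Ribosomal protein genes lay higher as a list, with none of 90 called, a median of 0.48 and a camera adjusted p = 4.92e-12, and with an estimated correlation adjusted p = 0.798. Camera also called the salicylate list (adjusted p = 0.0204, none called, 4 higher adjusted over the list alone), the flavonoid list (adjusted p = 0.0246), the histone list (adjusted p = 0.0347) and the proteinase inhibitor list (adjusted p = 0.0351), and with an estimated correlation adjusted p = 0.798, 0.783, 0.939 and 0.939. The salicylate and flavonoid calls ended with normexp (adjusted p = 0.102 and 0.201), the histone and proteinase inhibitor calls with quantile normalization (adjusted p = 0.142 and 0.129).

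At 72 h TC238749 was at least 8.98-fold higher after H-CSNP than after CSNP (adjusted p = 0.000351), BP902045 was higher by 3.38 ± 0.34 (adjusted p = 0.000123) and TC245073 by 3.15 ± 0.20 (adjusted p = 2.52e-05). TA39417_4081, similar to a proline-rich protein, was lower by 3.78 ± 0.78 (adjusted p = 0.0264), AW621470, similar to the virus resistance protein Tm-2, at least 3.22-fold lower (adjusted p = 0.0366) and AP2d lower by 0.93 ± 0.18 (adjusted p = 0.0196). The calls of AW621470 and AP2d ended with normexp (adjusted p = 0.485 and 0.0957), and omission of replicate 1 of the H-CSNP 72 h arrays ended those of TA39417_4081, AW621470 and AP2d (-2.89, -1.73 and -0.70, adjusted p = 0.263, 0.329 and 0.202). Without replicates 1 and 2 of CSNP 72 h TC238749 measured 2.79 and 4.63, both called. Limma called 509 probes, 436 higher and 73 lower, and 0 in a fit to the compared arrays alone. It called 178 with normexp, 273 and 1081 without replicates 1 and 2 of H-CSNP 72 h, and 3580 without replicate 2 of CSNP 72 h. CSNP at 72 h lay on the slide that also held H-CSNP at 24 h, and 256 of the 612 probes, TC238749, BP902045 and TC245073 among them, were called higher here.

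Over the 3 times together (6 arrays against 6), no gene with a product was called between treatments. PR-P2 and other PR genes gave a list median of -0.66 for H-CSNP against harpin, with a camera adjusted p = 1.88e-05 and, with an estimated correlation, an adjusted p = 0.741. Against CSNP the median was -0.64, with a camera adjusted p = 0.00214 and, with an estimated correlation, an adjusted p = 0.783. With slide as a fixed block camera placed this list higher (adjusted p = 0.000193 within that comparison). That fit has as many terms as groups and compares no groups of the same time. Its treatment term adds H-CSNP at 24 h minus CSNP at 72 h to the changes with time within the other slides. The turn in direction therefore cannot say how the treatments differ at the same time. Calcium genes were called against harpin (camera adjusted p = 0.0215, or 0.783 with an estimated correlation), a call that ended with normexp (adjusted p = 0.132) and with quantile normalization (adjusted p = 0.0818). Limma called 1 probe between H-CSNP and harpin, TA56870_4081, and 1 between CSNP and harpin, neither of which the sources used here pair with a product. TA56870_4081 was chosen after its values were seen. Between H-CSNP and CSNP limma called 0, with 1941 probes at an unadjusted p below 0.05.

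Changes with time could be measured within a slide, where an additive slide effect cancels. Under harpin some PR genes fell from 24 to 48 h. CK348294 fell at least 28.8-fold (adjusted p = 0.0153), PR-1a1 at least 6.78-fold (adjusted p = 0.0437) and PR-P2 by 2.30 ± 0.33 (adjusted p = 0.0102), with 1 of 2 other PR-P2 probes called lower. TA36002_4081 fell at least 8.85-fold (adjusted p = 0.00898) and P4 at least 6.79-fold (adjusted p = 0.0154). The list of 15 PR genes does not include PR-1a1, and 5 of its genes fell: the other 4 named here and NM_001247869 (adjusted p = 0.0157), which was dim at both times and was not called with a common floor (adjusted p = 0.886) or normexp (adjusted p = 0.419). Adjusted over the list alone 9 fell, with a median of -2.30 (-1.50 with normexp) and a camera adjusted p = 4.92e-12, and with an estimated correlation adjusted p = 0.00926. TCP3, a transcription factor of leaf growth, rose by 1.66 ± 0.20 (adjusted p = 0.00741), ARF5 by 1.27 ± 0.18 (adjusted p = 0.0102) and BP895717, similar to a cullin of protein turnover, by 1.52 ± 0.23 (adjusted p = 0.011). TA41966_4081, similar to a chloroplast small heat shock protein, rose at least 3.77-fold (adjusted p = 0.023), and 2 of 34 heat shock genes rose, 8 adjusted over the list alone, with a camera adjusted p = 0.00081, and with an estimated correlation adjusted p = 0.783. None of 11 chitinases was called at its brightest probe, and 5 fell adjusted over the list alone, with a camera adjusted p = 0.00219, and with an estimated correlation adjusted p = 0.602. CHI9 measured -2.07 (limma adjusted p = 0.053), with 3 of 4 other probes called lower, while 0 of 3 were for CHI3 and 0 of 4 for CHI17. PR1b1 measured -1.79 (limma adjusted p = 0.0847), with 2 of 5 other probes called lower. Limma called 198 probes, 118 higher and 80 lower, against 3 to 56 when any 1 array was left out and 14 higher and 48 lower with normexp. The normexp setting ended the calls of PR-1a1, TA36002_4081, P4, ARF5, BP895717 and TA41966_4081 (adjusted p = 0.144, 0.11, 0.203, 0.63, 0.222 and 0.542), and without the filter on dim probes that of PR-1a1 ended (adjusted p = 0.0768). Omission of replicate 1 of the harpin 48 h arrays ended the call of every gene named as called here, with -2.08 left for PR-P2.

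Under CSNP some PR genes rose from 24 to 48 h. PR-P2 rose by 2.53 ± 0.33 (adjusted p = 0.0108), with 0 of 2 other probes called by limma. TA36002_4081 rose at least 5.11-fold (adjusted p = 0.0285), and P4 was at least 3.67-fold higher without a call (adjusted p = 0.0506). NM_001247869 rose at least 2.18-fold (adjusted p = 0.00759), and with normexp its direction turned (adjusted p = 0.979). The calls of PR-P2 and TA36002_4081 ended with normexp (adjusted p = 0.184 and 0.606), and without replicate 2 of the CSNP 24 h arrays those of PR-P2, TA36002_4081 and NM_001247869 ended (adjusted p = 0.0948, 0.182 and 0.067). In a fit to the compared arrays alone PR-P2 was not called (adjusted p = 0.159), and without the filter on dim probes TA36002_4081 was not (adjusted p = 0.0552). Of the 15 PR genes 3 rose, and 4 adjusted over the list alone, with a median of 0.77 and a camera adjusted p = 0.000107, and with an estimated correlation adjusted p = 0.166, and with normexp the median turned to -0.06 and the list was not called (adjusted p = 0.225). ACI25 rose by 1.27 ± 0.21 (adjusted p = 0.035) and NM_001247460, a linker histone-like protein, by 1.39 ± 0.25 (adjusted p = 0.046). Both calls ended when any 1 array was left out (adjusted p up to 0.233 and 0.359), with normexp (adjusted p = 0.587 and 0.0601) and without the filter on dim probes (adjusted p = 0.0716 and 0.091). Limma called 60 probes, 30 higher and 30 lower, and 4 to 143 when 1 array was left out. None of 90 ribosomal protein genes was called, and camera placed the list lower (median -0.42, adjusted p = 2.68e-14), and with an estimated correlation adjusted p = 0.783.

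Under H-CSNP limma called 6 probes from 48 to 72 h, all higher and none paired with a product, with 2602 at an unadjusted p below 0.05, and with normexp 1, which was lower. It called 0 to 125 when 1 array was left out. ARPI measured -3.72 (adjusted p = 0.108). Proteinase inhibitor and wound genes lay lower as a list, with none called, 2 lower adjusted over the list alone and a camera adjusted p = 0.000266, and with an estimated correlation adjusted p = 0.783.

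Whether harpin and CSNP differed in their change from 24 to 48 h was tested as an interaction. PR-P2 fell under harpin and rose under CSNP, a difference of -4.84 ± 0.47 (adjusted p = 0.00174). On average over the pairs of groups, P4 was at least 4.99-fold and TA36002_4081 at least 6.72-fold lower at harpin 48 h and CSNP 24 h than at harpin 24 h and CSNP 48 h (adjusted p = 0.0084 and 0.00289). NM_001247869 was called lower too (adjusted p = 0.00174), with no bound, as it was dim at both times under harpin. Of the 15 PR genes these 4 were called, 6 adjusted over the list alone, with a median of -2.59 (-2.20 with dim members at their bound, -0.92 with normexp) and a camera adjusted p = 6.32e-16, and with an estimated correlation adjusted p = 0.00467. Photosynthesis genes gave a median of 0.45 (camera adjusted p = 0.00197, or 0.137 without saturated probes) and ribosomal protein genes a median of 0.47 (camera adjusted p = 4.16e-08), and with an estimated correlation adjusted p = 0.939 and 0.886. Limma called 9 probes, 3 higher and 6 lower, with PR-P2 on 2 of them, and 4 to 63 when 1 array was left out. With normexp 0 were higher and 3 lower, and with quantile normalization 11 were higher and 10 lower. The calls of P4, TA36002_4081 and NM_001247869 ended with normexp (adjusted p = 0.941, 0.941 and 0.973), that of NM_001247869 with a common floor (adjusted p = 0.218), and that of P4 without replicate 2 of harpin 24 h (adjusted p = 0.0568). Across all list tests, 82 were called by camera, and 3 of them held with an estimated correlation: the PR list in this interaction, in harpin from 24 to 48 h and in H-CSNP against CSNP at 48 h.

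**Figure D3:**
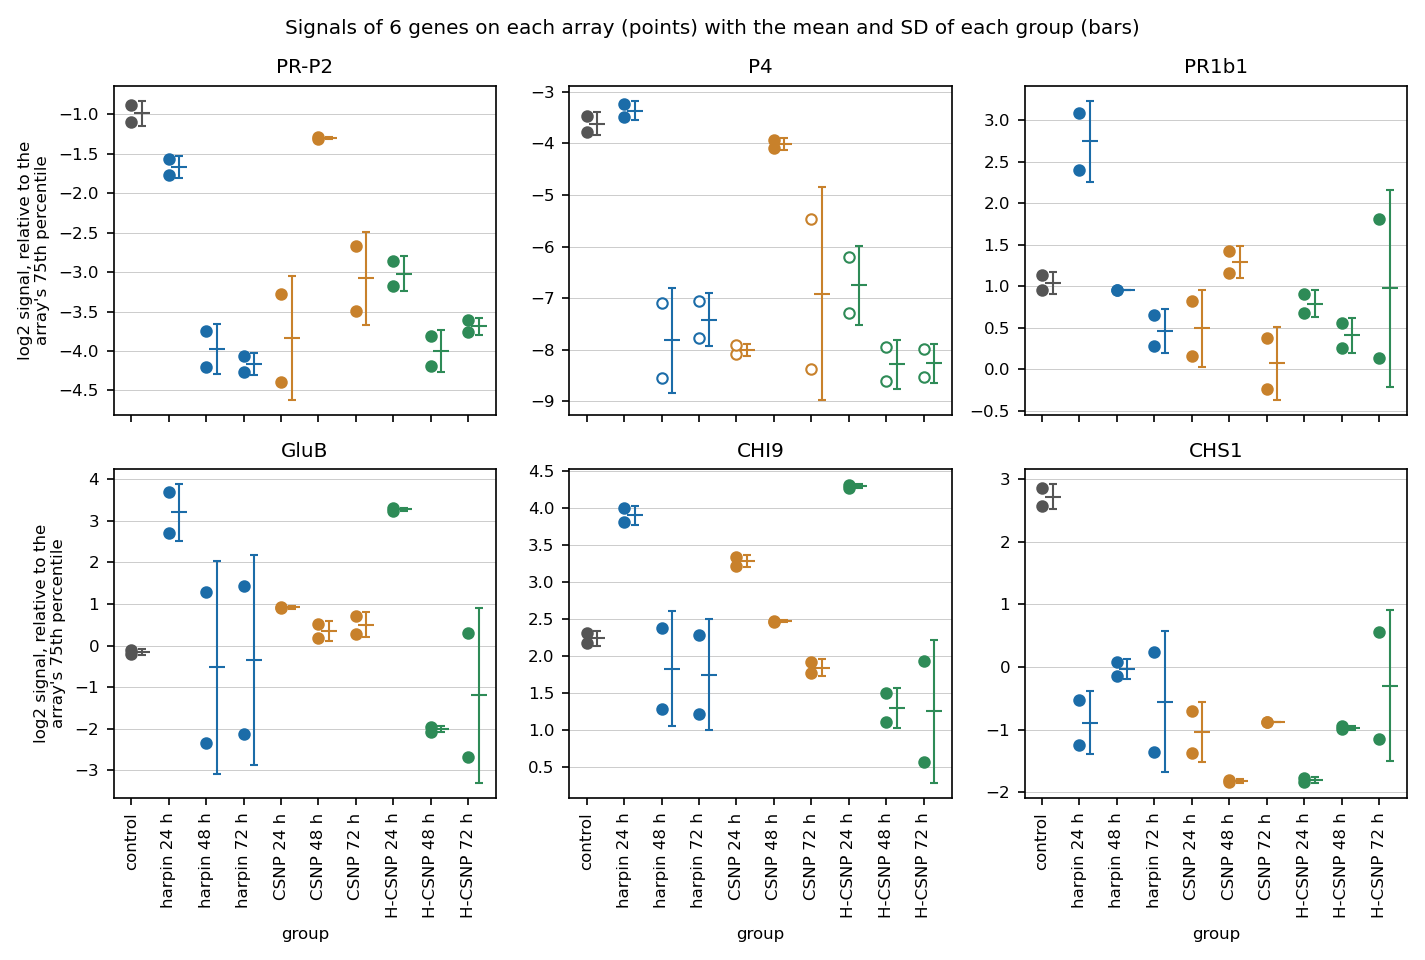
Normalised log2 level on each array (points, open where not well above background) and group mean with standard deviation (bars) of PR-P2, P4, PR1b1, GluB, CHI9 and CHS1 in the control and in each treatment at 24, 48 and 72 h. The PR-P2 mean is -0.99 in the control, falls from -1.67 to -3.97 under harpin and rises from -3.84 to -1.30 under CSNP between 24 and 48 h.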

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

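The tests of slide, labelling and treatment effects and of swapped labels in this part were chosen only after the result was seen, while the omission of single arrays and the brightness-matched lists were planned. The interaction of treatment and time called 9 probes whose change from 24 to 48 h differed between harpin and CSNP. Camera called 3 gene lists too, with medians of -2.59 for PR proteins, 0.45 for photosynthesis and 0.47 for ribosomal proteins. With an estimated correlation only the PR list was called, and the photosynthesis call also ended without saturated probes.

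PR-P2 fell from 24 to 48 h under harpin and rose under CSNP, with a difference of -4.84 ± 0.47. Each change lies within a slide, so an additive slide effect cancels and cannot give -4.84, and the omission of any 1 array left the call in place (highest adjusted p = 0.0189). Swapped labels of the CSNP 24 and 48 h arrays could not be settled, as the harpin and CSNP changes correlate at 0.077 over all probes, neither alike nor opposite. With normexp the CSNP change was 1.23 and was not called (adjusted p = 0.184), so the harpin fall carries more of the difference in that setting. A difference between the treatments stays open and was not tested further, with 2 arrays per group.

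Spike-in probes, which no comparison uses, separated the controls from all treated arrays. The brightest spike-in probe lay 7.62 (log2) higher on the lowest treated array than on the highest control array, and it measured -6.30 and -5.26 on control arrays. On treated arrays it measured 2.36 on replicate 1 of CSNP at 48 h and 4.75 to 6.36 on the others. That replicate also had the fewest spike-in spots well above background among treated arrays, 163 of 320 against 194 to 257. The control RNA may have been labelled without the spike-in, in another reaction, slide and scan, and no treated array shares these. The highest count between treated groups on different slides was 0.084 of the lowest count against the control, and 0.063 to 0.309 in 9 other settings. In separate fits to only the arrays compared, whose variances come from different arrays, it was 8401 against 600, a ratio of 14.0. The median absolute log2 fold change, which needs no variance, was up to 0.34 between these treated groups and at least 0.482 against the control. These values leave slide-to-slide differences open, and they, a difference in labelling and the treatments themselves cannot be told apart in these comparisons.

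Probes called lower in H-CSNP than in harpin at 24 h were also low in harpin and CSNP at 72 h. Over these 612 probes, a number that rests on all 4 arrays (187 to 237 called in all when 1 is left out), CSNP at 72 h, on the slide of H-CSNP at 24 h, lay at -0.78 relative to the slides with CSNP at 24 and 48 h and H-CSNP at 48 and 72 h. Harpin at 72 h, alone on another slide, lay at -0.90, so the slide is neither shown nor excluded as the cause. Group medians were -5.19 in harpin at 72 h, -5.09 in CSNP at 72 h and -5.28 in H-CSNP at 24 h, against -3.91 to -3.31 in the others. H-CSNP at 48 and 72 h differed from CSNP at 24 and 48 h by 0.12, so no lasting effect of H-CSNP was seen against CSNP. These groups lay on different slides, and at 48 h the group median was -3.91 in H-CSNP and -3.31 in harpin. A lasting effect is therefore neither shown nor excluded. BP902045, BG125071, BI934404, TC238749, TC245073 and TA57020_4081 were low in harpin at 72 h too, on another slide and without H-CSNP. BG125071 measured -3.84 in harpin at 72 h, -3.95 in CSNP at 72 h and -3.67 in H-CSNP at 24 h, and TC245073 -3.50, -3.26 and -2.77. For these genes an effect of H-CSNP at 24 h alone, or of its slide alone, leaves the low levels of harpin at 72 h unexplained. What these groups share was not tested.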

How the results depend on the processing

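Fits without the 72 h arrays, and for the gene lists normexp, quantile normalization and the omission of saturated probes, were chosen after seeing the data, and the tests of other settings before the data were examined. Calls are numbers of probes called by limma, in the order 24, 48 and 72 h where 3 are given, and where a setting moved a count beyond 1.5 times the cause was not tested unless stated.

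With normexp background correction, calls against the control were 7959, 5231 and 7595 for harpin, 6545, 8742 and 7532 for CSNP and 10088, 4094 and 4991 for H-CSNP. Between H-CSNP and harpin they were 148, 2 and 148, between H-CSNP and CSNP 53 at 48 h and 178 at 72 h. The overall comparisons of H-CSNP and of CSNP with harpin gave 0 and 0. Harpin from 24 to 48 h gave 62, CSNP 10, H-CSNP from 48 to 72 h 1 and the interaction 3. Direction turned in 3 gene results: PR-1a1 in H-CSNP at 24 h (-0.14, adjusted p = 0.831), TA44246_4081 in harpin at 48 h (-0.10, adjusted p = 0.871) and NM_001247869 in CSNP from 24 to 48 h (-0.035, adjusted p = 0.979). Of the other gene results 1017 kept direction and side of the threshold, 142 lost and 3 gained a call.

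In a fit to only the arrays compared, calls against the control were 6353, 2631 and 1996 for harpin, 4115, 6535 and 2492 for CSNP and 9976, 1781 and 600 for H-CSNP. Between H-CSNP and harpin they were 3618 at 24 h and 0 at 72 h, between H-CSNP and CSNP 8401, 756 and 0. Harpin from 24 to 48 h gave 983, CSNP 3, H-CSNP from 48 to 72 h 0 and the interaction 63. Of the gene results 819 kept, 199 lost and 39 gained a call.

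Without the 72 h arrays, which varied most among the treated arrays, H-CSNP against harpin gave 1693 and 663 calls at 24 and 48 h, and H-CSNP against CSNP 3490 and 1385. The overall comparisons gave 1377 (H-CSNP and harpin), 55 (H-CSNP and CSNP) and 619 (CSNP and harpin). Harpin from 24 to 48 h gave 1774, CSNP 363 and the interaction 282. Of the gene results 763 kept and 59 gained a call.

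With only probes well above background on all arrays, fewer probes were tested. H-CSNP against harpin gave 249, 21 and 203, H-CSNP against CSNP 67 at 48 h, the overall comparisons of H-CSNP and CSNP with harpin 0 and 0, CSNP from 24 to 48 h 102, H-CSNP from 48 to 72 h 0 and the interaction 1. With quantile normalization, H-CSNP against harpin at 48 h gave 143 and over all times 3, CSNP against harpin over all times 2, harpin from 24 to 48 h 341, CSNP 96, H-CSNP from 48 to 72 h 1 and the interaction 21. Without the filter on dim probes, H-CSNP against CSNP at 48 h gave 52, CSNP against harpin over all times 0, harpin from 24 to 48 h 120, CSNP 28 and H-CSNP from 48 to 72 h 3. With a common floor, H-CSNP against CSNP at 48 h gave 232, H-CSNP against harpin over all times 0, harpin from 24 to 48 h 407, CSNP 104 and the interaction 46. With eBayes with trend and robust, H-CSNP against harpin gave 201 at 48 h and 0 over all times, and CSNP from 24 to 48 h 101. Slide as a random block left 0 between H-CSNP and harpin over all times (consensus correlation 0.232). Gene results that lost a call were 24 with quantile normalization, 32 without the filter, 3 with only bright probes, 6 with a common floor and 6 with eBayes with trend and robust. The deposited series matrix kept all 1165.

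Replicate numbers did not pair the arrays: over 45 pairs of groups the replicate differences correlated at a median of 0.007 (-0.313 to 0.325, 4 above 0.1 and 8 below -0.1). With a replicate block CSNP against harpin overall gave 0 calls, and 13 gene results lost a call.

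Camera called 82 list results, 3 with an estimated correlation, 53 with quantile normalization, 83 with normexp, 64 without saturated probes and 101 with fry, which is no competitive test.

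With 1 array left out, the lone array of a group is assumed to vary like the other groups. Calls against the control then ranged from 8733 to 16200, 4651 to 13308 and 8244 to 15684 for harpin, 6545 to 14770, 10125 to 16684 and 9001 to 16300 for CSNP, and 10448 to 18009, 3724 to 10386 and 6190 to 13499 for H-CSNP. H-CSNP against harpin ranged from 187 to 237, 79 to 130 and 241 to 846, and H-CSNP against CSNP from 165 to 264, 0 to 174 and 273 to 3580. Over all times they ranged from 0 to 221 (H-CSNP and harpin), 0 to 0 (H-CSNP and CSNP) and 0 to 108 (CSNP and harpin). Harpin from 24 to 48 h ranged from 3 (without replicate 1 of harpin 48 h) to 56, CSNP from 4 to 143, H-CSNP from 48 to 72 h from 0 to 125 and the interaction from 4 to 63. Of 632 named-gene calls against the control 527 stayed in each of these fits and 105 ended in at least 1, and of 86 between treated groups or times 24 stayed and 62 ended.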

Other observations

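In this part the comparison of chance splits and of brightness-matched lists was planned, and no test was chosen only after the result was seen. Splits of the 12 arrays of each overall comparison into 6 and 6 were drawn 100 times, the real one included, with time as a term in each fit. Between H-CSNP and harpin 11 splits called at least the 1 probe of the real split, with 732 as the highest other count, so chance cannot be excluded. Between CSNP and harpin 9 splits did, with 149 as the highest other count against 1, so chance cannot be excluded there either. Between H-CSNP and CSNP all 100 did, since limma called 0 in the real split (1941 at an unadjusted p below 0.05), and the highest other count was 4925. Of the 99 other splits 10, 8 and 7 called any probe. What gave the split with 4925 calls was not tested.

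As a list, ribosomal protein genes lay lower in the treated arrays by camera at its preset correlation. With an estimated correlation camera called this list in none of the 9 comparisons with the control. A scanner response that depends on brightness was tested with 10000 random lists matched on brightness. Of these 0 had a median as low as the -0.83 of the 90 ribosomal genes over the 9 comparisons, with -0.17 as their median and -0.46 as the lowest. The labelling of the controls and the treatments stay open, and no biological explanation was tested.

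The arrays at 72 h varied most among the treated ones. The replicate standard deviation was 0.477 for harpin, 0.49 for CSNP and 0.479 for H-CSNP at 72 h, against 0.197 to 0.37 at 24 and 48 h and 0.542 in the control. Replicate 1 of CSNP at 72 h was scanned on another day than the other treated arrays. Its replicate spots varied most, with a median coefficient of variation of 13.2% against at most 8.6% on the other arrays. It also had the most outlier spots, 51 against at most 18. Of all arrays, 5 correlated more closely with an array of another group than with their own replicate: both of harpin at 72 h, replicate 2 of CSNP at 72 h and both of H-CSNP at 72 h.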
